A study of Mus musculus with 12 samples.

How the data were processed

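The deposited table held raw counts of reads per gene for all 12 libraries, 23086 gene symbols by 12 columns, each column matched to a library by its name. Per the labels, RNA was extracted from embryoid bodies with a column kit and libraries were made with the TruSeq RNA Sample Prep Kit. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.33, TopHat2 2.1.1 and the mm10 genome were used, and limma is also named. The counting tool, the gene annotation and whether counting used strand are not given in the sources used here. Antisense and overlapping genes can therefore share counts, and members of gene families with near-identical copies (*Zscan4c* and *Zscan4f*, *Hist1h3d*, the Y-linked genes and their X-linked relatives) can lose or share reads, so their values are uncertain.

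Total counts ran from 4289984 to 4850393 per library. At this depth genes with a few counts have wide counting intervals and small changes in rare transcripts were not detectable. Of these symbols 4753 had no count in any library. Spreadsheet software had turned 27 symbols into dates, 2 of which occurred more than once. They held 0.150% of all counts, stayed in the fit, and are not named. Mitochondrially encoded transcripts were not analysed here. Gene positions came from the GENCODE M21 annotation of the same genome, matched by symbol, for 12194 of the genes tested (99.0%).

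Groups were taken from the sample titles, which give line, treatment and replicate. All pairs of replicates of 1 group differed by more than sampling noise in a chi-square test of their counts (lowest chi-square per degree of freedom 1.11), so none were merged. That test does not tell separate cultures from separate preparations of 1 culture.

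The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts as deposited, with TMM scaling, the filterByExpr filter (a minimum count of 10, which is 2.18 CPM here, and a total of 15) and robust estimation. All 12 libraries were fitted together with 1 mean per group, which left 12322 genes holding 99.8% of the counts. The 5 comparisons were doxycycline against none in each line, the difference of these responses, and the lines against each other without and with doxycycline. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Standard errors are the size of the log2 fold change divided by the square root of the F statistic. Such an error restates the test result, and it can be too small where a group held few counts. Levels are CPM, counts scaled to a common size of TMM-adjusted libraries. Where a group held 1 to 3 counts of a gene, the ratio is given with a 95% exact counting interval, and where it held 0 a floor of 3 counts over the group was used.

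Gene lists were tested with limma's camera (limma 3.58.1, voom values, preset correlation 0.01), adjusted over the 22 lists with at least 5 tested members. Beside it stand camera with a correlation estimated from the data, fry, and counts of members adjusted over the list alone. The lists, the comparisons, the tests and the alternatives were fixed before the data were examined. They covered head organizer and anterior mesendoderm, LHX1 cofactors and LIM proteins, naive and formative pluripotency, primitive streak, definitive endoderm, neural ectoderm, targets of the WNT, NODAL, BMP and FGF pathways, adhesion, ATF4, hypoxia, p53 and cholesterol genes. Markers of extraembryonic endoderm, trophoblast, germ cells, two-cell-like cells, fibroblasts, and blood and endothelium were included as other cell types. Some genes stand in several lists (*Hesx1*, *Foxa2*, *Cyp26a1*, *Eomes*), so the lists are not independent. Lists of interferon, Notch and retinoid genes were added after the values were seen, with camera adjusted over their 15 tests, and over 24 tests of the interferon list with and without genes and libraries.

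Genes were named by a rule: *Lhx1* in every comparison, the 6 called genes with the largest rise and the 6 with the largest fall that had at least 1 CPM in the higher group and no overlap between the groups' libraries, leaving out predicted genes and small RNAs, and from each list up to 3 called members with the smallest adjusted p in the wild-type response and up to 2 in the other comparisons. A gene named in 1 comparison may be given values in the others, and 1 gene that met the rule is not reported here. *Hprt*, *Rn45s*, *Bnip3* and *Adm* were singled out after their values were seen, as were the genes of the closing section that no comparison names. The same holds for *Gata4*, *Cubn*, *Dab2*, *Cited1* and *Pth1r*.

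The test was tested on simulated counts drawn from the means and library sizes of these libraries, with all 12322 genes in the step and 50 genes changed per fold size. In the wild-type response 68% of genes changed 1.5-fold, 84% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 4.03% of calls were false. In the mutant response these values were 74%, 92%, 98% and 3.90%, and in the difference of responses 50%, 82%, 88% and 7.03%.

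Alternatives were DESeq2's size factors and upper-quartile scaling in edgeR, the DESeq2 Wald test (version 1.42.0), limma-voom, no filter and a stricter filter (at least 1 CPM in 3 libraries and a mean of 5), only the libraries compared, the replicate number as a block, each library left out in turn, and a test against a minimum fold of 1.5. After the data were seen, fits without the *Rn45s* row, without both libraries that stood apart (wild-type library 3 without and library 2 with doxycycline), and with a hypoxia score per library as a covariate were added. The score was a mean log2 level of hypoxia genes.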

Results

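The series asked which genes respond to LHX1, a LIM homeodomain transcription factor required for formation of the head. Total RNA was sequenced from embryoid bodies, aggregates in which embryonic stem cells begin to differentiate, grown for 2 days from mouse stem cells of the A2lox.cre type. In such cells a gene placed at the *Hprt* locus on the X chromosome is switched on by the antibiotic doxycycline. One line carried *Lhx1* fused to the FLAG tag, a short peptide that an antibody recognises, and the other carried a mutant form of FLAG-*Lhx1* whose change is not given in the sources used here. Embryoid bodies of each line were kept without doxycycline or treated with it for 16 h, giving 4 groups of 3 libraries. The 12 libraries held 4289984 to 4850393 counts each. Values below are means ± SD of 3 libraries in CPM (counts scaled to a common library size), or log2 fold changes with a standard error (SE). The SE is taken from the F statistic of the test.

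In a principal component analysis the lines separated along the first component (59.2% of the variance), and doxycycline separated the libraries of both lines along the second (9.0%). There the wild-type libraries lay at 14.4 to 16.5 without and −16.3 to −13.3 with doxycycline, and the mutant ones at 0.611 to 2.08 and −2.60 to −1.15. In the analysis without *Lhx1* and *Hprt*, added after this was seen, the mutant groups overlapped (−1.17 to 0.624 and −0.937 to 0.676). Libraries of 1 group were not equal in every respect. *Rn45s*, the ribosomal RNA precursor, took 1.45% of the counts in wild-type library 2 with doxycycline and 0.0884% to 0.265% in the other 11. *Bnip3*, a mitochondrial protein induced by low oxygen, reached 229 CPM in wild-type library 3 without doxycycline, against 58.5 and 63.3 in the other libraries of that group. *Adm*, the hypoxia-induced hormone adrenomedullin, stood at 10.98 there against 0.476 and 1.36. Wild-type library 3 with doxycycline was also high (*Bnip3* 107 against 52.1 and 65.8 CPM), while the mutant libraries ranged from 83.4 to 148.

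*Lhx1* (chromosome 11, 84518284 to 84525535, mm10) rose with doxycycline in both lines. In the wild-type line it went from 2.09 ± 1.13 to 296 ± 9.37 CPM, a log2 fold change of 7.15 (SE 0.12, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.86e-48). In the mutant line it went from 0.421 ± 0.0124 to 248 ± 12.6, a log2 fold change of 9.11 (SE 0.15, edgeR adjusted p = 4.55e-48). Without doxycycline the wild-type libraries held 14, 8 and 5 *Lhx1* counts and the mutant libraries 2 each. At so few counts the SEs of both rises understate the uncertainty of their size. The difference between the rises had an SE of 0.49. Under doxycycline the wild-type line had the higher level, by 0.25 on the log2 scale (SE 0.05, edgeR adjusted p = 6.93e-05). The counts do not tell transgene from endogenous transcripts, and reads of the mutant form are counted only where they still align to the gene.

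**Figure D1:**
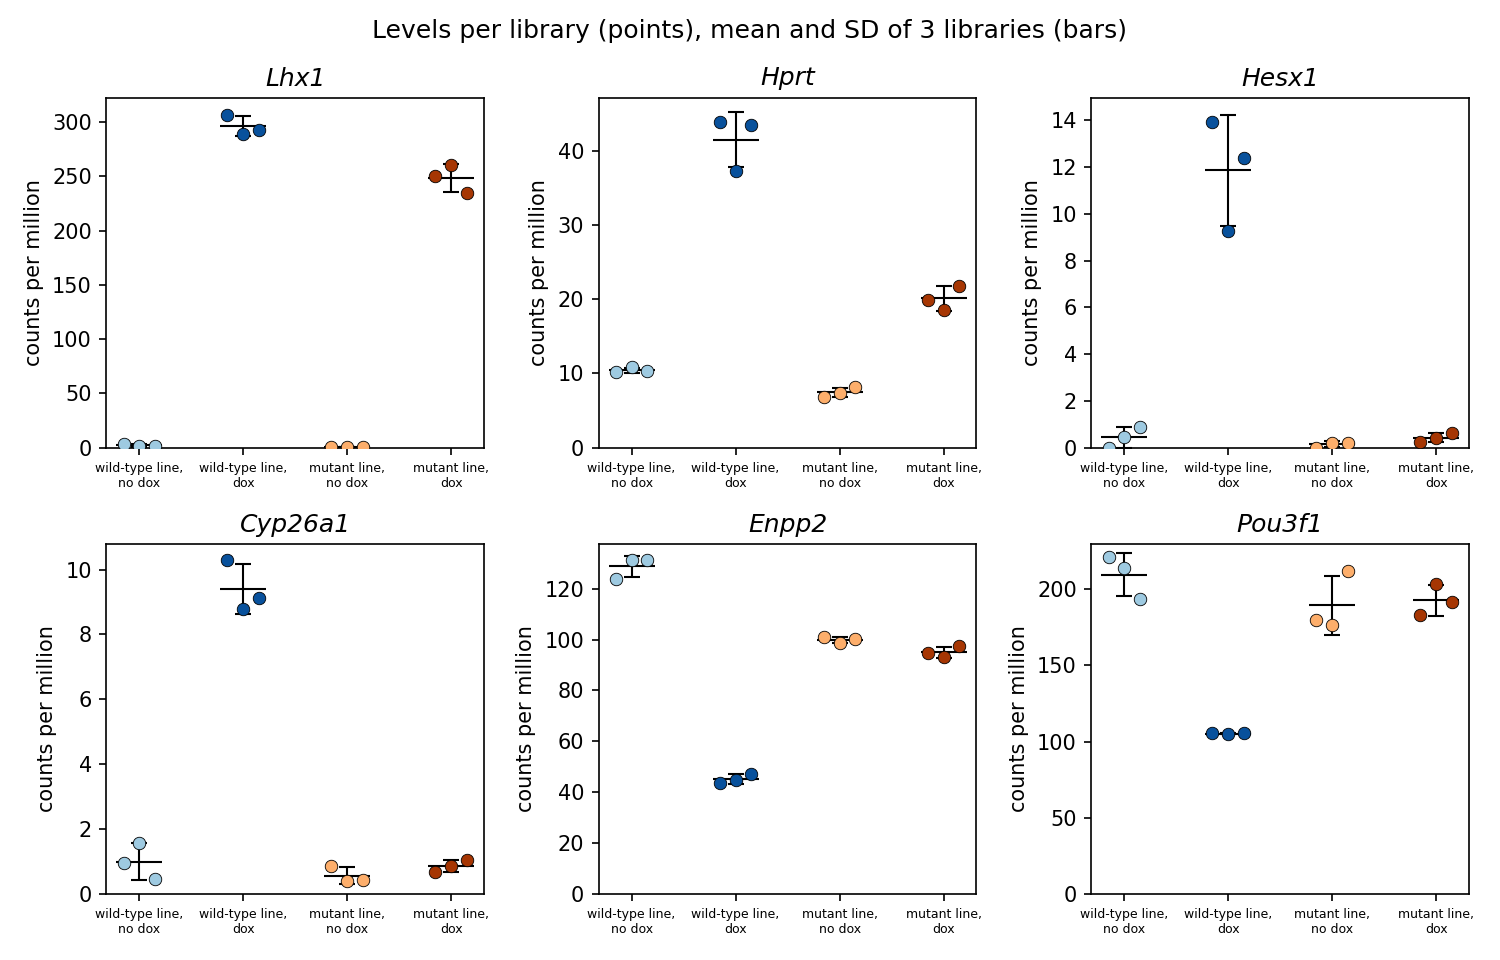
CPM of 6 genes in each of the 12 libraries (points), by line and treatment, with the mean and SD of 3 libraries (bars) and all axes starting at 0. *Lhx1* and *Hprt* were higher with doxycycline in both lines, *Hesx1* and *Cyp26a1* were higher and *Enpp2* and *Pou3f1* lower with doxycycline in the wild-type line.

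Induction of wild-type FLAG-*Lhx1* was followed by the appearance of transcripts that were close to absent before. *Hesx1* (chromosome 14, 26994416 to 27002329), a homeobox repressor of the anterior neural plate and pituitary, rose from 0.450 ± 0.448 to 11.9 ± 2.38 CPM (log2 fold change 4.62, SE 0.39). *Foxa2* (chromosome 2, 148042877 to 148046969), a forkhead factor of the node, notochord and endoderm, rose from 2 to 38 counts over 3 libraries, a ratio of 18.9 with a 95% counting interval of 4.87 to 161. *Lmo1*, a LIM-only protein, rose by a log2 fold change of 3.21 (SE 0.56), and *Cdh20*, a cadherin, by 3.40 (SE 0.60). The counting interval covers counting error only. The SEs, taken from the F statistic, can be too small for genes with so few untreated counts.

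The steepest falls in the wild-type line were those of *Ebf1*, a helix-loop-helix factor of B cells and neurons (log2 fold change −2.07, SE 0.44), and *Ndnf*, a secreted neurotrophic factor (−2.04, SE 0.48). *Tmem145* (−1.72, SE 0.32), *Ccdc160* (−1.67, SE 0.36) and *Kirrel2*, an adhesion molecule of the immunoglobulin family (−1.67, SE 0.26), fell less. *Ccdc160* lies within 1 Mb of *Hprt* and had −1.06 (SE 0.31, edgeR adjusted p = 0.613) in the mutant line, with no overlap between the groups' libraries. *Ddx60*, a helicase of antiviral defence, fell by 1.67 (SE 0.37), but by 1.26 with edgeR adjusted p = 0.0664 once wild-type library 3 without doxycycline was left out. Among more abundant transcripts, *Enpp2* (chromosome 15, 54838901 to 54952892), the enzyme that makes lysophosphatidic acid, fell from 129 ± 4.23 to 45.2 ± 1.89 CPM (log2 fold change −1.51).

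In all, 655 of 12322 genes tested differed with doxycycline in the wild-type line, 340 higher and 315 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 107 of these by at least 2-fold, 78 higher and 29 lower. Of the 655 genes, 640 had no overlap between the groups' libraries, as had 18.9% of all genes tested, where chance gives 10%. DESeq2 called 380 genes, and without both libraries that stood apart 543 were called, 432 of them among the 655. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

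Several genes of the organizer and anterior mesendoderm, the tissues that pattern the head, rose in the wild-type line. The list held 25 genes, of which 15 passed the filter, and the rest had too few counts to be tested. Of 15 tested members 7 rose, 1 fell and 7 were not called (7 and 3 adjusted over the list alone). *Otx2* was among those not called (log2 fold change 0.04, edgeR adjusted p = 0.865). Besides *Hesx1* and *Foxa2*, *Cyp26a1*, which degrades retinoic acid, rose from 0.994 ± 0.568 to 9.40 ± 0.784 CPM (log2 fold change 3.21, SE 0.33). *Sfrp1*, a secreted WNT antagonist, rose by 0.77. *Gpc4*, a heparan sulfate proteoglycan, rose by 1.16 (SE 0.14), and it lies within 1 Mb of *Hprt*, which rose with doxycycline in both lines. The list as a whole was higher (camera adjusted p = 6.07e-06), with adjusted p = 0.0461 with an estimated correlation, and it was the only one of the 8 lists called in this comparison that kept its call there.

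Several neural genes and *Eomes* were also higher. Of 10 tested genes of the neural ectoderm and anterior neural plate 5 rose and 1 fell, the same numbers as adjusted over the list alone. *Pax6*, a regulator of the eye and forebrain, rose by 1.32 (SE 0.22), and *Zic2*, a zinc finger factor of the forebrain, by 0.34 (SE 0.06). The list was called higher by camera (adjusted p = 0.00278), which was lost at adjusted p = 0.0614 with an estimated correlation and 0.0579 without a filter. Of the 5 tested genes of the primitive streak and mesoderm 1 rose and 4 were not called, also when adjusted over the list alone. It was *Eomes*, a T-box factor needed for endoderm and anterior mesoderm, at 9.38 ± 2.21 and 28.9 ± 5.34 CPM (log2 fold change 1.62, SE 0.15). The list, of which 20 of 25 genes were not tested, had a camera adjusted p of 0.00278, lost at adjusted p = 0.0943 with an estimated correlation and 0.217 without a filter.

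Pluripotency and epiblast genes moved in both directions. Of 20 genes of naive pluripotency 4 rose, 7 fell and 9 were not called (5 and 9 adjusted over the list alone). *Fgf4*, a growth factor of the early epiblast, fell by 0.39 (SE 0.06), *Dppa5a* fell by 0.21 (SE 0.04), and *Zfp42*, a marker of naive cells, rose by 0.32 (SE 0.06). Of 19 genes of the formative and primed epiblast 3 rose, 6 fell and 10 were not called (4 and 7 adjusted over the list alone). *Pou3f1* (chromosome 4, 124656807 to 124660655), a POU factor that promotes neural fate, fell from 210 ± 14 to 105 ± 0.469 CPM, and *Dnmt3a*, a DNA methyltransferase, fell by 0.58 (SE 0.04). *Fgf5*, a marker of the primed epiblast, rose from 86.4 ± 4.91 to 159 ± 7.89. Both lists were called lower by camera (adjusted p = 0.0446 each), with adjusted p = 0.622 and 0.535 with an estimated correlation. The naive list lost its call (camera adjusted p 0.0740 to 0.205) without wild-type libraries 1 or 2 of either treatment, and the formative list (0.0679 to 0.114) without library 1 of either treatment or library 3 with doxycycline. With the replicate block they had 0.0538 and 0.0528.

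Feedback genes of signalling pathways showed single strong changes. *Dusp4*, a phosphatase that restrains ERK, rose from 107 ± 8.13 to 210 ± 2.25 CPM, and *Egr1*, an immediate early gene, fell by 0.63 (SE 0.17). These were the 2 of 18 FGF and ERK genes called, also when adjusted over the list alone. *Id3*, a BMP-induced inhibitor of helix-loop-helix factors, rose by 1.55 (SE 0.12) while its relative *Id2* fell by 0.64 (SE 0.15), and 8 of 10 BMP genes were not called (1 rose and 1 fell, also adjusted over the list alone). *Ccnd2*, a G1 cyclin, rose by 1.95 (SE 0.15) and *Lef1*, a nuclear WNT effector, fell by 0.46 (SE 0.09), among 2 genes that rose and 2 that fell of 12 WNT genes (3 and 2 adjusted over the list alone). *Skil*, a repressor of SMAD signalling, fell by 0.59 (SE 0.08), among 2 that rose and 2 that fell of 13 NODAL genes (2 and 4 adjusted over the list alone). None of these 4 lists was called as a whole (camera adjusted p = 0.292, 0.211, 0.746 and 0.864). The call of *Egr1* was lost without wild-type library 1 or 2 of either treatment (edgeR adjusted p 0.0741 to 0.131) and in DESeq2 (0.0797).

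Cell surface genes changed without a common direction. Of 20 adhesion and guidance genes 5 rose, 4 fell and 11 were not called (6 and 5 adjusted over the list alone, camera adjusted p = 0.419). *Ephb1*, an ephrin receptor, rose from 1.61 ± 0.638 to 8.89 ± 0.760 CPM, *Cdh3*, P-cadherin, rose by 0.80 (SE 0.09), and *Sema6a*, a transmembrane semaphorin, fell by 0.67 (SE 0.09). Of 8 tested LHX1 cofactors and LIM proteins only *Lmo1* was called by edgeR (1 and 1 adjusted over the list alone, camera adjusted p = 0.962), and of 10 definitive endoderm genes only *Foxa2* (also adjusted over the list alone, camera adjusted p = 0.746).

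Among markers of other cell types, laminin genes and *Sparc* rose. Of 13 primitive and extraembryonic endoderm genes 4 rose and 9 were not called (5 and 1 adjusted over the list alone). Among those not called, *Gata4* (−0.89), *Cubn* (−0.77) and *Dab2* (−0.55) lay below 0, and *Cited1* (0.86) and *Pth1r* (0.76) above. The members thus did not move together, and the list does not tell whether such cells increased. *Lama1* rose by 0.83 (SE 0.18), *Lamb1* by 0.38 (SE 0.07) and *Sparc*, a matrix glycoprotein, by 0.31 (SE 0.06), of which *Lama1* and *Sparc* lost their calls without both libraries that stood apart (edgeR adjusted p = 0.103 and 0.0689). The list had a camera adjusted p of 0.0137, with adjusted p = 0.0943 with an estimated correlation, and 0.0548 without wild-type library 2 of the untreated group. No member of the trophoblast (5 genes), germ cell (9), two-cell-like (7), fibroblast (8) or blood and endothelium (6) lists was called by edgeR, with 1, 1, 0, 1 and 0 called when adjusted over the list alone and camera adjusted p = 0.927, 0.864, 0.927, 0.927 and 0.927.

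The calls of *Gapdh*, *Nupr1* and *Bax* among stress genes depended on single libraries. Of 23 hypoxia and glycolysis genes 1 was called, *Gapdh*, which fell by 0.15 (SE 0.04), also when adjusted over the list alone. Camera called the list lower (adjusted p = 0.00278, and adjusted p = 0.798 with an estimated correlation), but its direction turned to higher without wild-type library 3 of the untreated group, the one with high *Bnip3* (adjusted p = 0.408), and without both libraries that stood apart (0.0520). *Gapdh* had an edgeR adjusted p of 0.105 without the first and 0.188 without both, and 0.0724 and 0.0547 without library 2 or 3 with doxycycline. The list call was also lost without wild-type library 1 with doxycycline (camera adjusted p = 0.114), and that of *Gapdh* in limma-voom (0.0987) and with only the libraries compared (0.0772). With the hypoxia score the list had camera adjusted p = 0.147, but that score is itself a mean of hypoxia genes and takes out the list's own signal. Of 22 targets of ATF4, the factor of the integrated stress response, only *Nupr1* rose by edgeR (log2 fold change 1.26, SE 0.37; 2 adjusted over the list alone). Camera called that list higher at adjusted p = 0.0446, with adjusted p = 0.622 with an estimated correlation, 0.0528 with the replicate block, 0.0579 without a filter and 0.120 to 0.294 without wild-type libraries 1 or 2 of the untreated group or 1 or 3 with doxycycline. Camera adjusted p was lower, at 0.000475, without both libraries that stood apart, 0.00249 without library 2 with doxycycline, 0.0141 without untreated library 3 and 0.00822 with the hypoxia score. *Nupr1* lost its call in DESeq2 (adjusted p = 0.253) and without 4 single libraries (0.112 to 0.2004), namely 2 and 3 of the untreated group and 1 and 3 with doxycycline. Of 16 p53 targets *Pmaip1*, a BCL2 antagonist, rose by 0.40 and *Bax* fell by 0.16 (2 and 3 adjusted over the list alone, camera adjusted p = 0.927), and *Bax* lost its call without any 1 wild-type library but library 1 with doxycycline (edgeR adjusted p 0.0544 to 0.257), without both libraries that stood apart (0.281), with only the libraries compared (0.101), upper-quartile scaling (0.0670) or the replicate block (0.0640), and in DESeq2 (0.191). None of 20 cholesterol synthesis genes was called by edgeR, also when adjusted over the list alone (camera adjusted p = 0.927). For the WNT, definitive endoderm, LIM protein and trophoblast lists the median and camera's direction differed in sign, and for the NODAL list the mean and camera's direction did.

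In the mutant line only *Lhx1* and *Hprt* were called, both higher. *Hprt* (chromosome X, 52988137 to 53021659), the purine salvage enzyme next to which these lines carry their transgene, rose from 7.44 ± 0.636 to 20.1 ± 1.63 CPM (log2 fold change 1.43, SE 0.16, edgeR adjusted p = 5.79e-09). In the wild-type line it rose from 10.5 ± 0.339 to 41.6 ± 3.70 (log2 fold change 1.99, SE 0.13, edgeR adjusted p = 1.70e-18). *Hesx1* held 2 and 6 counts over 3 mutant libraries without and with doxycycline, a ratio of 3.03 (95% counting interval 0.542 to 30.7). *Foxa2* stood at 0.425 ± 0.220 and 0.425 ± 0.369, *Cyp26a1* at 0.565 ± 0.255 and 0.847 ± 0.186, *Eomes* at 18.4 ± 1.66 and 18.9 ± 1.56, and *Pou3f1* at 189 ± 19.6 and 193 ± 10.2 CPM.

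Of 12322 genes 578 had an unadjusted p under 0.05 in the mutant line, where chance gives 616.1, and DESeq2 and limma-voom also called 2 genes. Fitted on its 6 libraries alone, the mutant line gave 5 calls, 2 higher and 3 lower. No list had a called member by edgeR, and 1 member each of the FGF, ATF4 and trophoblast lists was called when adjusted over the list alone. Camera called the naive pluripotency (adjusted p = 0.0496), hypoxia (0.0282) and two-cell-like (0.0282) lists lower, each with adjusted p = 0.698 with an estimated correlation. Without mutant library 3 of the untreated group the 3 lists had camera adjusted p = 0.296, 0.510 and 0.296, and without library 3 with doxycycline 0.0917, 0.964 and 0.0757. The naive list also lost its call without library 2 of either treatment (0.230 and 0.178) and with the replicate block (0.0552), and the two-cell-like list without library 2 with doxycycline (0.212). Without a filter the 3 lists had 0.0818, 0.0926 and 0.111, and with the hypoxia score the direction of the hypoxia list turned to higher (0.0553). As the score is itself a mean of hypoxia genes, that fit does not test the hypoxia list. For the other 19 lists camera adjusted p lay above 0.05. Median and mean, or mean and camera's direction, differed in sign for the organizer, definitive endoderm, FGF and adhesion lists.

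The change with doxycycline differed between the lines for genes of several kinds. *Ccnd2* (difference of the log2 fold changes 2.35, SE 0.24), *Ephb1* (2.02, SE 0.38), *Eomes* (1.58, SE 0.21), *Id3* (1.48, SE 0.16), *Dusp4* (1.25, SE 0.10) and *Fgf5* (0.91, SE 0.08) had the higher change in the wild-type line. *Slc18a3*, the vesicular acetylcholine transporter (3.85, SE 1.00), *Robo3*, an axon guidance receptor (3.08, SE 0.87), *Dusp26*, a phosphatase (2.54, SE 0.63), and *Hist1h3d*, a replication-dependent histone (2.36, SE 0.50), lay on the same side. Part of these differences came from falls in the mutant line that were not called (−1.08, −1.19, −0.59 and −1.21). *Hist1h3d* was not called in the wild-type line either (1.15, edgeR adjusted p = 0.0726). *Enpp2* (−1.44, SE 0.09), *Cxcl12*, a chemokine (−1.68, SE 0.21), *Tmem145* (−1.91, SE 0.42), *Kirrel2* (−1.47, SE 0.35), *Ntrk2*, a neurotrophin receptor (−1.40, SE 0.34), and *Pou3f1* (−1.02, SE 0.09) had the lower one there. Without doxycycline *Ccnd2*, *Ephb1*, *Eomes*, *Id3* and *Fgf5* were already higher in the mutant than in the wild-type libraries, and *Dusp4* was lower. *Fgf5* stood at 167 to 181 CPM in untreated mutant libraries, against 151 to 166 in treated wild-type ones. *Id3* stood at 37.8 to 45.1 against 44.4 to 52.0. *Lhx1* itself had a difference of −1.97 (SE 0.49, edgeR adjusted p = 0.0212), since its level without doxycycline was lower in the mutant line by 2.22 on the log2 scale. It rests on the 6 counts of the untreated mutant libraries: the call was lost without any 1 of them (adjusted p 0.0626 to 0.0908), without wild-type library 1 of the untreated group (0.281), in limma-voom (0.0838) and in DESeq2 (0.111).

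The test of this difference called 307 genes by edgeR, 173 with the higher change in the wild-type line and 134 with the lower one. DESeq2 called 153, and 292 were called without both libraries that stood apart. The organizer list differed (4 members higher, 1 lower and 10 not called of 15; 7 and 1 adjusted over the list alone; camera adjusted p = 2.93e-05, and adjusted p = 0.0626 with an estimated correlation), with *Sfrp1* (0.83) and *Gpc4* (1.38) among its called members. *Hesx1* (3.18, SE 1.63, edgeR adjusted p = 0.406), *Foxa2* (3.998, SE 1.23, 0.0690) and *Cyp26a1* (2.63, SE 0.81, 0.0695) were not called by the test of the difference. The neural list differed too (3 higher, 1 lower and 6 not called of 10; 4 and 1 adjusted over the list alone; camera adjusted p = 0.00458, and adjusted p = 0.0678 with an estimated correlation), with *Pax6* (1.36, SE 0.31) and *Gbx2*, a midbrain-hindbrain homeobox factor (1.62, SE 0.41). In the streak list *Eomes* alone was called of 5 (also adjusted over the list alone; camera adjusted p = 0.0133, and adjusted p = 0.161 with an estimated correlation), and the list lost its call without wild-type library 1 with doxycycline (camera adjusted p = 0.0667). In the extraembryonic endoderm list *Lamb1* alone was called of 13 (0.43, SE 0.10; 6 and 1 adjusted over the list alone; camera adjusted p = 0.0133, and adjusted p = 0.0911 with an estimated correlation). Without a filter the neural, streak and endoderm lists had camera adjusted p = 0.260, 0.506 and 0.179.

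Some lists had called members but no call as a whole in the test of the difference. These were the formative (3 higher and 6 lower of 19, the same numbers as adjusted over the list alone), naive (2 and 3 of 20; 6 and 4 adjusted over the list alone) and adhesion lists (5 and 3 of 20; 5 and 4 adjusted over the list alone), with camera adjusted p = 0.324, 0.609 and 0.505. The NODAL (1 and 2 of 13; 2 and 2 adjusted over the list alone), WNT (1 and 1 of 12; 2 and 2), BMP (1 and 0 of 10; 1 and 1) and FGF lists (1 and 0 of 18; 1 and 1) had camera adjusted p = 0.609, 0.534, 0.505 and 0.377. *Zic2* (0.26), *Cdh3* (0.58), *Dnmt3a* (−0.61), *Skil* (−0.51), *Sema6a* (−0.65), *Fgf4* (−0.36) and *Pou5f1*, a core pluripotency factor (−0.26), were among the genes called. The calls of *Robo3*, *Slc18a3*, *Lef1* (−0.47), *Ntrk2*, *Gbx2*, *Dusp26*, *Kirrel2* and *Dppa5a* (−0.24) were each lost without at least 1 single library, with edgeR adjusted p up to 0.138, 0.180, 0.0886, 0.0539, 0.0697, 0.154, 0.116 and 0.0683. These libraries were untreated wild-type library 3 (*Lef1*, *Ntrk2*, *Gbx2*), treated wild-type library 1 (*Lef1*, *Ntrk2*) or 3 (*Lef1*), untreated mutant library 1 (*Dusp26*, *Dppa5a*), 2 (*Slc18a3*, *Lef1*) or 3 (*Slc18a3*), treated mutant library 1 (*Slc18a3*, *Dusp26*), 2 (*Kirrel2*) or 3 (*Lef1*, *Gbx2*, *Dusp26*), and for *Robo3* any of 9 libraries. In DESeq2 *Pax6*, *Lef1*, *Ntrk2*, *Gbx2* and *Kirrel2* had adjusted p = 0.0669, 0.184, 0.0849, 0.120 and 0.0584, and *Robo3* and *Slc18a3* were given none. Without both libraries that stood apart *Ntrk2* and *Gbx2* had edgeR adjusted p = 0.0679 and 0.125. No member of the LIM, definitive endoderm, ATF4, hypoxia, p53, cholesterol or remaining cell type lists was called by edgeR, with 1, 1, 0, 0, 3, 0 and 0 called when adjusted over the list alone. The mean and camera's direction differed in sign for the naive and NODAL lists, and the median and camera's direction for the WNT and BMP lists.

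Called genes of the lines overlapped in *Lhx1* and *Hprt*, both higher, and in no lower gene. By chance 0.0552 shared higher genes would be found (Fisher's exact test, one-sided p = 0.000759). Since *Lhx1* is the induced gene and *Hprt* lies next to the transgene in both lines, this test does not tell whether the responses overlap otherwise. Of the other 653 genes called in the wild-type line, 322 (49.3%, 95% Wilson interval 45.4% to 53.2%) had the same sign in the mutant line, and 278 (42.6%) were also called by the test of the difference, which shares the wild-type libraries. The 340 higher and 315 lower genes had median log2 fold changes of 0.53 and −0.40 in the wild-type line and −0.018 and −0.018 in the mutant line. Across all genes, which are not independent replicates, Pearson's r between the responses was 0.0792, and −0.00687 without *Lhx1* and *Hprt*. Spearman's rho over all genes was −0.0299. The responses share no library.

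**Figure D2:**
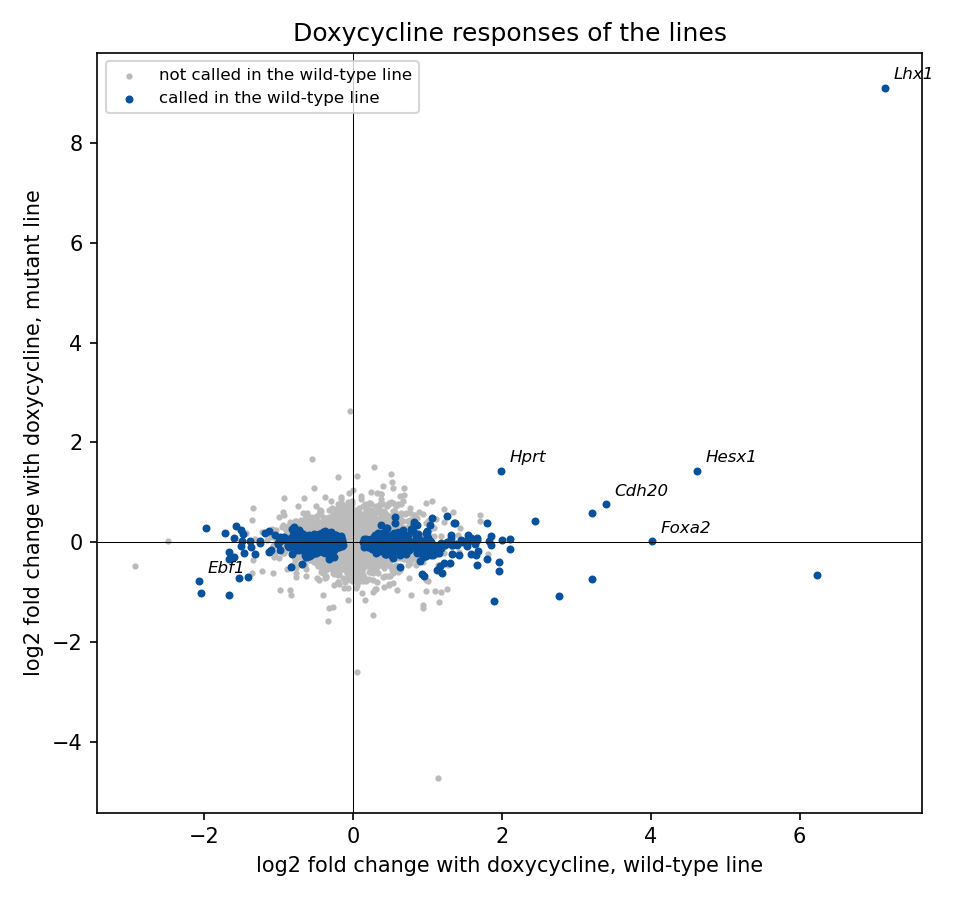
Log2 fold change with doxycycline of each tested gene in the wild-type line (horizontal axis) and in the mutant line (vertical axis), with the 655 genes called in the wild-type line in blue. *Lhx1* and *Hprt* lie high on both axes. *Foxa2*, *Hesx1* and *Cdh20* lie far from 0 on the horizontal axis. *Hesx1* lies about as high as *Hprt* on the vertical axis, but there it rests on 2 and 6 counts over 3 libraries.

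Without doxycycline the lines already differed widely. Genes of naive pluripotency were higher in the wild-type line, 15 of 20 higher, 2 lower and 3 not called, the same numbers as adjusted over the list alone. *Zfp42* stood at 179 ± 10.5 CPM against 46.1 ± 3.54 in the mutant line (log2 difference 1.96, SE 0.07), *Dppa3*, a maternal factor of naive and germ cells, at 17.8 ± 1.45 against 3.71 ± 1.00, and *Fgf4* at 160 ± 5.01 against 84.9 ± 7.96. Of 19 formative and primed genes 4 were higher, 10 lower and 5 not called (4 and 11 adjusted over the list alone), with *Sall2* at −1.36 (SE 0.05) and *Fgf5* at −1.001 (SE 0.06). Single genes lower in the wild-type line were *Tagln* at 13.5 ± 0.864 against 124 ± 11 CPM, *Acta2* at −2.56 (SE 0.19), *Actc1* at −4.64 (SE 0.32) and *Nes*, an intermediate filament of neural progenitors, at −1.94 (SE 0.07). Camera called both epiblast lists (adjusted p = 6.34e-06 higher and 0.00204 lower), each with adjusted p = 0.207 with an estimated correlation.

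Metabolic genes differed too. Of 22 ATF4 targets 12 were higher in the wild-type line and none lower by edgeR, also when adjusted over the list alone, led by *Mthfd2*, a mitochondrial folate enzyme (1.39, SE 0.07), and *Slc7a5*, an amino acid transporter (0.87, SE 0.05; camera adjusted p = 0.00115, and adjusted p = 0.236 with an estimated correlation). Of 23 hypoxia and glycolysis genes 6 were lower, 17 were not called and none was higher, also when adjusted over the list alone, with *Ldha* at −0.80 (SE 0.10) and *Pfkl* at −0.98 (SE 0.13; camera adjusted p = 0.00114, and adjusted p = 0.577 with an estimated correlation). *Bnip3* was at 109 to 148 CPM in the untreated mutant libraries, against 58.5, 63.3 and 229 in the untreated wild-type libraries. Of 9 germ cell genes 4 were higher (also adjusted over the list alone; camera adjusted p = 0.0350, and adjusted p = 0.207 with an estimated correlation), among them *Dppa3* and *Dppa4*. Of 10 definitive endoderm genes 4 were lower (also adjusted over the list alone; camera adjusted p = 0.0350, and adjusted p = 0.236 with an estimated correlation), led by *Cldn6* (−0.99) and *Trh* (−1.21), and of 13 extraembryonic endoderm genes 1 was higher and 7 lower (2 and 7 adjusted over the list alone; camera adjusted p = 0.0409, and adjusted p = 0.207 with an estimated correlation), led by *Apoe* (−0.88) and *Sparc* (−0.62). The endoderm calls were lost without untreated wild-type library 2 (camera adjusted p = 0.0838 each) or mutant library 1 (0.0525 and 0.0718), the definitive one also without mutant library 3 (0.0523) and the extraembryonic one without mutant library 2 (0.0512). Without a filter both had 0.0582.

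Other lists had called members without a call as a whole. Higher and lower genes numbered 0 and 5 of 15 in the organizer list (also adjusted over the list alone), led by *Gpc4* (−1.52) and *Otx2* (−0.59), 2 and 3 of 8 in the LIM list (*Rlim* 0.93, *Ssbp3* −0.60; also over the list alone), 0 and 2 of 5 in the streak list (*Eomes* −0.97, *Wnt3* −1.31; also) and 1 and 5 of 10 in the neural list (also). They numbered 4 and 4 of 12 in the WNT list (*Notum* 1.96, *Ccnd1* −0.28; also adjusted over the list alone), 1 and 6 of 13 in the NODAL list (*Ltbp1* −1.22; also), 0 and 2 of 10 in the BMP list (*Id3* −1.37, *Smad7* −0.29; 0 and 1) and 5 and 8 of 18 in the FGF list (*Etv4* 1.09, *Dusp6* −0.70; also). In the adhesion list they numbered 3 and 7 of 20 (*Robo1* −0.95; 3 and 8 adjusted over the list alone), among p53 targets 3 and 5 of 16 (*Trp53inp1* −0.31; also) and in cholesterol synthesis 4 and 9 of 20 (*Fdft1* −0.65, *Hmgcs1* −0.32; also). Cell type lists held 0 and 1 of 5 trophoblast genes (*Krt8* −0.47; also), 0 and 2 of 7 two-cell-like genes (*Zscan4f* −0.81, *Zscan4c* −0.61; 0 and 1), 1 and 2 of 8 fibroblast genes (*Tagln*, *Acta2*; also) and 2 and 1 of 6 blood and endothelium genes (*Pecam1* 1.11, *Etv2* −1.65; also). Camera adjusted p of these 15 lists lay from 0.101 to 0.903. *Smad7*, *Wnt3*, *Zscan4c* and *Zscan4f* lost their calls without untreated wild-type library 3 (edgeR adjusted p = 0.301, 0.0553, 0.208 and 0.101). *Smad7* also lost its call without wild-type library 2 or mutant library 1 or 3 (0.0797 to 0.139) and in DESeq2 (0.118). *Zscan4c* and *Zscan4f* also lost theirs without mutant library 3 (0.328 and 0.139) and in DESeq2 (0.163 and 0.0667). The call of *Zscan4c* rested near the threshold, with adjusted p 0.0501 to 0.0629 under either other scaling, in limma-voom, without a filter, with only the libraries compared, with the replicate block and without wild-type library 1. For the blood and endothelium list the median and camera's direction differed in sign.

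By edgeR 5611 of 12322 genes differed between the untreated lines, 2779 higher and 2832 lower in the wild-type line, 808 of them by at least 2-fold, 347 higher and 461 lower. Y-linked genes were among the largest differences: *Ddx3y* stood at 146 ± 5.45 against 0.489 ± 0.105 CPM and *Eif2s3y* at 210 ± 9.48 against 1.26 ± 0.350, while *Kdm5d* was at least 19.2-fold and *Zfy1* at least 31.9-fold higher in the wild-type line against 0 counts in the mutant one (floor of 3 counts over the group). The imprinted gene *Plagl1* was at least 13.8-fold higher. On chromosome 8 the median log2 difference was 0.39, on chromosome 11 0.19 and on chromosome 14 −0.49, against −0.074 to 0.044 on the other autosomes and X. Leaving out chromosomes 8, 11, 14 and Y, 4318 of 10101 genes (42.7%) were still called. The genes and lists named in the comparisons of the lines, with and without doxycycline, were not separated by chromosome. Members on chromosomes 8, 11 or 14 may therefore differ with their region.

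**Figure D3:**
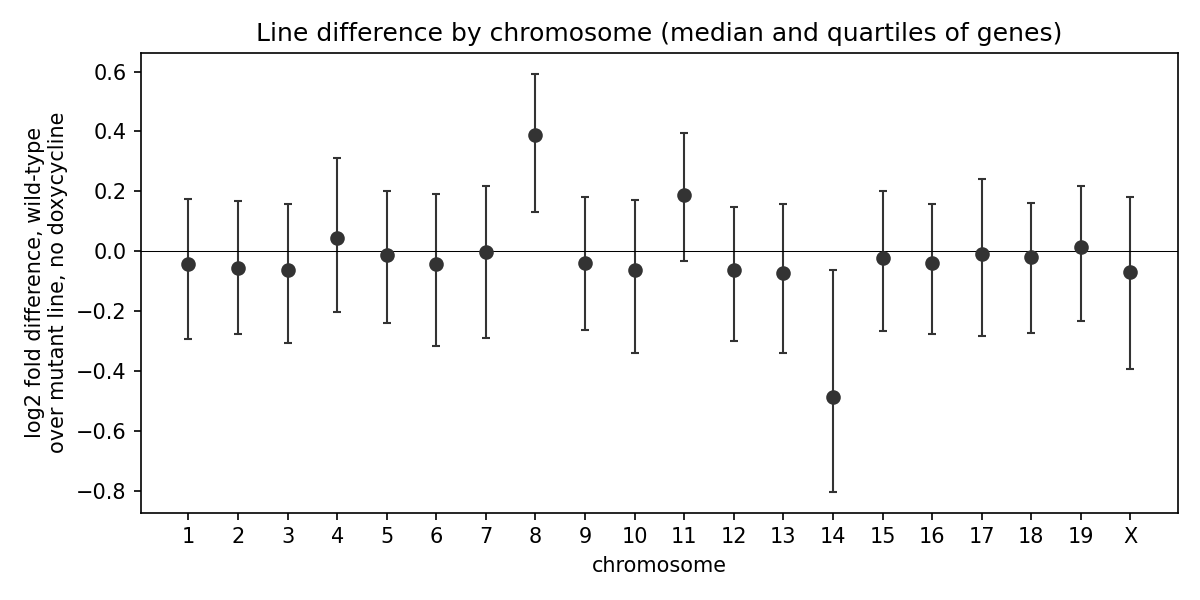
Median (points) and quartiles (bars) of the log2 difference, wild-type over mutant line without doxycycline, of the tested genes on each chromosome except Y. Chromosome 8 (0.39) and chromosome 11 (0.19) lie above the others and chromosome 14 (−0.49) below.

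Under doxycycline the lines differed in 5466 genes by edgeR, 2763 higher and 2703 lower in the wild-type line, 864 of them by at least 2-fold, 417 higher and 447 lower. *Hesx1* (4.72, SE 0.38), *Cyp26a1* (3.42, SE 0.33), *Ccnd2* (1.69, SE 0.15) and *Dusp4* (1.58, SE 0.07) were higher in the wild-type line, as were *Zfp42* (2.30, SE 0.07) and the Y-linked *Ddx3y* (8.94, SE 0.18), which differed before. *Sema6a* (−1.45, SE 0.08), *Sall2* (−1.93, SE 0.06) and *Tagln* (−3.21, SE 0.09) were lower, and *Dlg2*, a synaptic scaffold, held 1 count against 50, a ratio of 46.8 in favour of the mutant line (95% counting interval 8.02 to 1884). This comparison holds the difference between the lines as well as that between the forms of LHX1.

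The lists called under doxycycline were those of naive pluripotency (15 higher and 2 lower of 20; camera adjusted p = 2.00e-05, and adjusted p = 0.272 with an estimated correlation), the formative epiblast (2 and 10 of 19; 9.48e-05, and adjusted p = 0.272 with an estimated correlation) and ATF4 targets (14 and 1 of 22; 0.000116, and adjusted p = 0.286 with an estimated correlation). So were hypoxia and glycolysis (0 and 9 of 23, or 0 and 8 adjusted over the list alone; camera adjusted p = 0.000116, and adjusted p = 0.616 with an estimated correlation) and germ cells (4 and 0 of 9; 0.0420, and adjusted p = 0.272 with an estimated correlation). The germ cell call was lost without mutant library 2 or 3 with doxycycline (camera adjusted p = 0.0596 and 0.0532). Of the organizer list 7 genes were higher and 5 lower of 15 (7 and 6 adjusted over the list alone), and its median and camera's direction differed in sign. Higher and lower genes numbered 3 and 2 of 8 LIM proteins, 1 and 1 of 5 streak, 2 and 4 of 10 definitive endoderm, 5 and 2 of 10 neural, 3 and 3 of 12 WNT (4 and 3 adjusted over the list alone), 4 and 7 of 13 NODAL, 0 and 1 of 10 BMP, 5 and 8 of 18 FGF, 5 and 7 of 20 adhesion, 1 and 5 of 16 p53 and 4 and 5 of 20 cholesterol genes. They numbered 3 and 5 of 13 extraembryonic endoderm, 0 and 1 of 5 trophoblast, 0 and 1 of 7 two-cell-like (0 and 0 adjusted over the list alone), 0 and 3 of 8 fibroblast and 1 and 1 of 6 blood and endothelium genes. Where no second count is given, that adjusted over the list alone was the same, and camera adjusted p of the 17 lists not called lay from 0.167 to 0.851. Median or mean and camera's direction differed in sign also for the LIM, streak, BMP, adhesion, two-cell-like and blood lists.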

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

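The tests on *Hprt* and its neighbours, on chromosomes, on the Y-linked sum and on the hypoxia score were chosen only after the result was seen. Results are given here because the change with doxycycline differed between the lines by the test of the difference itself.

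That test called 307 genes. In 100 of the 200 possible splits of each treatment group's 6 libraries into sets of 3, 2 splits called at least as many genes, the real one included, and the highest other split called 1240. That split put all 3 untreated wild-type libraries but 1 of the 3 treated ones under the wild-type label. Another split of the same make-up called 32 genes, so the make-up alone does not account for the count. A count several times the real one may still come from a structure of the samples, such as the difference between the lines. Since the other splits mixed lines that differ in 5611 genes, the line difference enters their counts, and these splits cannot tell whether chance can be excluded for the difference of the responses. For the wild-type response (655 genes) the highest other of 10 splits called 1. For the mutant response (2 genes) the highest other called 2. For the lines without doxycycline (5611) and with it (5466) the highest other called 0. Sets of 10 splits are too few for a share under 0.05.

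The first pattern is the 655 calls in the wild-type line against 2 in the mutant line. The median standard error in the mutant line was 0.961 times that of the wild-type line. It cannot tell whether the mutant line had less power, since 1 fit gave all groups a shared spread. With only the libraries compared, the wild-type line gave 549 calls and the mutant line 5. The same response at a smaller size is argued against by the 49.3% of genes with the same sign and a slope of 0.00373 (95% interval −0.0136 to 0.0211) of the mutant on the wild-type changes. A difference in hypoxia between libraries as the whole cause is argued against by the 93.1% of the 655 genes that stayed called with the hypoxia score as a covariate. What also stays open is whether the mutation or the state of its line accounts for the pattern: each form of *Lhx1* is in 1 line, and the lines differ in 5611 genes without doxycycline, so these cannot be told apart. A loss of function of the mutant protein may explain the pattern, as a hypothesis that a second line of each kind would test.

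The second pattern is the rise of *Hprt* in both lines beside neighbours whose median lay below 0. The 10 tested genes within 1 Mb had median log2 fold changes of −0.39 in the wild-type and −0.25 in the mutant line, with 8 and 10 of them below 0, and no neighbour was called in the mutant line by edgeR (lowest adjusted p = 0.237). Among 12004 windows of 10 consecutive genes the mutant median lay at percentile 0.0750 and the wild-type one at 0.0250, but these neighbours prompted the pattern, so the ranks restate it and a local effect of the induced cassette at *Hprt* stays open. A shift of the whole X chromosome is argued against by the other 437 X genes, with a median of −0.0195 in the mutant line (95% bootstrap interval −0.0353 to −0.00534). In the wild-type line 6 neighbours were called, of which *Gpc4* and *Gpc3* rose and *Ccdc160*, *Phf6*, *Fam122b* and *Zfp36l3* fell, so whether *Gpc4* responds to LHX1 or to its place stays open, although in the mutant line it stood at −0.23 (edgeR adjusted p = 0.999).

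The third pattern is the line difference on chromosomes 8, 11, 14 and Y. All 12 segments of 10 Mb of chromosome 8 with at least 20 tested genes (100%) had medians above 0.2 with and without doxycycline. An extra copy in part or all of the wild-type cells, or a loss in mutant cells, could give this, and the ratio does not tell which. A whole-chromosome change of 14 is argued against, since 62.5% of its segments (5 of 8) had medians below −0.2, while those from 20 to 40 Mb had 0.020 and 0.0084 without doxycycline. A partial loss in the wild-type line, a partial gain in the mutant line or a regional effect may remain. A library under the wrong line is argued against by the Y-linked sum, where the lowest wild-type library (446 CPM) stood 66.4 times above the highest mutant one (6.72). The segments of chromosome 11 had medians of 0.116 to 0.263 without doxycycline, and these chromosomes cover 1240 of the 5611 genes called, so most of the line difference lies elsewhere.

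Of single genes, *Slc18a3* had a difference of the log2 fold changes of 3.85, *Robo3* of 3.08, *Dusp26* of 2.54, *Hist1h3d* of 2.36, *Ccnd2* of 2.35 and *Ephb1* of 2.02, the change being higher in the wild-type line. Differences between 1 and 2 were those of *Gbx2* (1.62), *Eomes* (1.58), *Id3* (1.48), *Gpc4* (1.38), *Pax6* (1.36) and *Dusp4* (1.25). Smaller ones were those of *Fgf5* (0.91), *Sfrp1* (0.83), *Cdh3* (0.58), *Lamb1* (0.43) and *Zic2* (0.26). Several of these genes, such as *Fgf5*, *Id3* and *Gpc4*, were already higher in the untreated mutant than in the untreated wild-type line, while *Dusp4* was lower. The change with doxycycline, not the level, was lower in the wild-type line for *Lhx1* (−1.97), *Tmem145* (−1.91), *Cxcl12* (−1.68), *Kirrel2* (−1.47), *Enpp2* (−1.44), *Ntrk2* (−1.40) and *Pou3f1* (−1.02). Smaller negative differences were those of *Sema6a* (−0.65), *Dnmt3a* (−0.61), *Skil* (−0.51), *Lef1* (−0.47), *Fgf4* (−0.36), *Pou5f1* (−0.26) and *Dppa5a* (−0.24). Among lists, the organizer (camera adjusted p = 2.93e-05), neural (0.00458), primitive streak (0.0133) and extraembryonic endoderm (0.0133) lists differed between the lines, and none of these 4 calls held with an estimated correlation (adjusted p 0.0626 to 0.161).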

How the results depend on the processing

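The fits without the *Rn45s* row, without both libraries that stood apart and with the hypoxia score were chosen after seeing the data. Counts moved by over 1.5 times in these cases. DESeq2 called 380 genes in the wild-type response and 153 in the difference, and the test against a minimum fold of 1.5 called 65, 32, 788 (lines with doxycycline) and 749 (without), as a stricter null hypothesis must. The mutant response had 5 calls (2 higher, 3 lower) with only the libraries compared. Leaving out 1 library gave 501 to 599, 2 to 2, 229 to 322, 4748 to 4957 and 4914 to 5140 calls in the wild-type, mutant, difference, treated and untreated comparisons, and the overlap stayed at 2 in all fits. Without both libraries that stood apart 543 (432 of the 655) and 292 genes were called, with the hypoxia score 684 (610 of the 655), 3 and 384, and without the *Rn45s* row 650, 2, 308, 5466 and 5614. Scaling moved the share of higher calls by under 10 percentage points. *Lhx1* kept its calls except in the difference, where it had −2.04 in DESeq2, −1.67 in limma-voom and −2.27 to −1.48 without 1 library. With only the libraries compared, the filter removed *Lhx1* from the untreated comparison, which then has no value. The cause was not tested, except that fewer samples bear on the left-out libraries.

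List calls moved most. In the wild-type response 8 lists were called, and 1 with an estimated correlation, 5 without a filter and 4 to 7 without 1 library. In the mutant response (3) there were 0 with an estimated correlation, 0 with fry, 0 without a filter, 5 with the hypoxia score and 0 to 4 without 1 library. In the difference (4) there were 0 with an estimated correlation, 1 without a filter, 7 without both libraries that stood apart and 3 to 5 without 1 library. With doxycycline (5) there were 0 with an estimated correlation, 16 with fry, which asks another question, and 4 to 5 without 1 library, and without doxycycline (7) 0, 14 and 5 to 7. Of the genes that the rule names in each comparison, *Lhx1* aside, none reversed, and 31 of 38, 1 of 1, 17 of 26, 49 of 51 and 49 of 53 kept their calls in each fit of their comparison that gave them a value, the minimum fold aside (a filter removed some, and the stricter one left 133 of 169).

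Replicate numbers gave no sign of pairing: the 18 same-numbered pairs had correlations of −0.0712 to 0.0794, none over 0.1, and 7 of 36 best matches were the own number. Deviations from group means hold much counting noise at this depth, so this check cannot exclude pairing. The replicate block gave 618, 2, 286, 5354 and 5502 calls, and 5 lists in the wild-type response. Depth limits the rarest genes: the filter, with its bound of 2.18 CPM, left rarer transcripts untested in the main fit. Without a filter 719 genes were called in the wild-type response, 634 of them among the 655.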

Other observations

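The lists of interferon, Notch and retinoid genes, and all tests on them, were chosen only after the result was seen. Genes of the interferon response and antigen processing were lower with doxycycline in the wild-type line. *Pml*, a nuclear body scaffold induced by interferon, had a log2 fold change of −0.64 (SE 0.05), *Irf1*, an interferon regulatory factor, −0.69 (SE 0.07), *Parp12* −0.87 (SE 0.12), the peptidase *Erap1*, which trims antigens, −0.78 (SE 0.15), the immunoproteasome subunits *Psmb8* −0.93 (SE 0.25) and *Psmb10* −0.47 (SE 0.08), and *Tapbp*, which loads peptides, −0.59 (SE 0.11). The membrane proteins *Ifitm1* (0.90, SE 0.07), *Ifitm2* (0.56, SE 0.06) and *Ifitm3* (0.75, SE 0.09), which block viral entry, rose instead. Of 39 tested genes 13 fell, 3 rose and 23 were not called by edgeR, and 31 lay below 0.

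Of 16 Notch genes 3 rose and 2 fell in the wild-type line, with *Rbpj*, the nuclear effector, at 0.62 (SE 0.05), the ligand *Dll3* at 1.13 (SE 0.16) and the ligands *Dll1* at −1.11 (SE 0.19) and *Jag1* at −0.58 (SE 0.17), and the list did not stand apart (camera adjusted p = 0.736). Of 11 retinoid genes *Cyp26a1* and the receptor *Rxrg* (1.80, SE 0.16) rose and the receptor *Rara* fell by 0.47 (SE 0.10), and that list did not stand apart either (camera adjusted p = 0.736).

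A hypothesis is that wild-type LHX1, directly or not, may lower a basal interferon programme. The whole list had a camera adjusted p of 5.23e-07, and adjusted p = 0.00758 with an estimated correlation, without allowance for having been picked from the data. Without *Parp9*, *Parp12*, *Irf1*, *Ddx60*, *Oasl2*, *Gbp2* and *Psmb8*, the 7 genes that prompted it, 6 of 32 fell and 3 rose (camera adjusted p = 0.00192, and adjusted p = 0.0284 with an estimated correlation). Without untreated wild-type library 3 these values were 0.00473 and 0.0604, and without both libraries that stood apart 0.0434 and 0.0773. A response to doxycycline shared by both lines is argued against by the median in the mutant line, 0.0153, against −0.27 in the wild-type line. The test of the difference gave camera adjusted p = 0.0260 without the prompting genes, adjusted p = 0.0801 with an estimated correlation, and 0.140 without both libraries that stood apart. The list was also higher in the untreated wild-type line (23 higher and 2 lower of 39, median 0.52), so a response to doxycycline that only the wild-type line can show stays open, as neither line was measured without its transgene. Both comparisons use the untreated wild-type libraries, so a high level in these alone would give both results. Between the lines under doxycycline the list had a median of 0.33 (camera adjusted p = 0.102).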
